A study of Homo sapiens with 18 samples.

How the data were processed

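Gene expression was measured by RNA sequencing in 18 libraries from A549, a lung cancer cell line, and MDA-MB-231, a breast cancer cell line. Per the labels' protocols, cells grown in medium with 10% serum were transfected with a control siRNA or with siRNAs against BLM, and total RNA was made into stranded libraries after ribosomal RNA removal (Illumina TruSeq, Ribo-Zero Gold). The protocols name both flat culture at 80% confluence and 3D culture on day 4, and the labels do not tell which applies to which library. All libraries of a line were treated as 1 culture type, which is an assumption. The labels give each library a cell line, an siRNA and a number from 1 to 3, which set the 6 groups of 3. That siRNA1 is the same siRNA in both lines is assumed from its shared name in the labels. Nothing states that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

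The deposited files hold expected counts, TPM and FPKM for 27968 gene symbols per library. The expected counts are RSEM estimates of reads per gene, per the file headers and the submitters' processing notes, which name RSEM and the hg19 genome. The RSEM version, the aligner and the annotation release are not given in the sources used here. The deposited TPM values are scaled to transcript length and to a fixed total per library, per the file headers, and served as an alternative. The deposited FPKM values, per the file headers also scaled to length and depth, were not used here. Between 10.2% and 11.8% of expected counts, zeros included, were not whole (any decimal other than 0, with no tolerance), because RSEM shares reads between similar transcripts, so genes with near-identical copies or readthrough partners are uncertain. The totals ran from 30143047 to 40328208 per library, and the 10 most abundant genes took 3.93% to 7.13% of the counts.

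Expected counts were rounded to whole numbers. Tests used edgeR 4.0.16 in R 4.3.3 with TMM scaling, the filterByExpr filter (minimum count 10, minimum total 15) and the quasi-likelihood F test, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The 12 A549 libraries shared 1 fit, the 6 MDA-MB-231 libraries another, and the difference of the siRNA1 effect between the lines was tested as an interaction in the 12 libraries concerned. The fits had group means only. Log2 fold changes are given with standard errors, and CPM values as mean and SD over 3 libraries.

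Of 23 gene lists fixed before the data were examined, 22 were tested: BLM partners and RecQ helicases, homologous recombination and Fanconi anaemia, p53 targets, DNA replication and G1/S, G2/M and mitosis, replication-dependent histones, interferon-stimulated genes, NF-kB and inflammatory cytokines, the integrated stress and unfolded protein responses, cholesterol synthesis, hypoxia and glycolysis, NRF2 targets, epithelial junction and keratin genes, mesenchymal genes, extracellular matrix and integrins, ribosomal proteins, RNA interference machinery, immediate early genes, and markers of leukocytes, fibroblasts, alveolar type 2 cells and luminal breast cells. The mitochondrially encoded list had 0 of its 13 members in the files. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists within a comparison, beside camera with an estimated correlation and fry. The genes named in the text follow a rule fixed at the same time: BLM; the 10 highest and 10 lowest for the A549 mean among genes changed the same way by all 3 siRNAs; the 5 highest and 5 lowest per A549 siRNA; the 10 highest and 10 lowest in MDA-MB-231; the 10 higher and 10 lower genes with the largest smaller change in both lines; the 5 highest and 5 lowest of the interaction; the 3 highest and 3 lowest between siRNAs; and up to 4 members per list and comparison with the smallest adjusted p. Except for BLM and list members, a named gene needed an average log2 CPM of at least 1, and not all are printed. Some results under this rule are not reported here.

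Alternatives were DESeq2 size factors and upper quartile factors, no filter on low counts and a filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, limma-trend on log2 of TPM plus 1 or plus 0.1, the replicate number as a block, only the 2 groups compared, all 18 libraries, a model of 9 siRNA against 3 control libraries, a minimum absolute log2 fold change of 1, and leaving out each library. Chance agreement among comparisons with shared controls came from 20 simulations of unchanged groups. On simulated counts with 200 changed genes, the A549 siRNA1 test of 15587 genes recovered 68.7% of changes of 1.5-fold, 95.5% of 2-fold and 100% of 4-fold, with 20 other genes called. The MDA-MB-231 test of 15146 genes recovered 88.1%, 100% and 100%, with 15 others called. The interaction test of 16295 genes recovered 44.8%, 83.6% and 100%, with 6 others called. In the real A549 siRNA1 comparison 11404 of 15898 genes were called, and scaling and recovery under such broad change were not tested.

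Transcript sequences of the GENCODE reference on GRCh38 were used for sequence composition and 3' UTRs, and no coordinates were used, since the files use another build. All 7-base words of 3' UTRs present in at least 100 of 12708 genes were ranked by the fold change of genes with and without them. Replicate pairs of a group were compared by chi-square, and the lowest value per degree of freedom was 2.79, so none differed by as little as sampling noise. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used.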

Results

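RNA sequencing measured gene expression in A549 lung cancer cells given a control siRNA or 1 of 3 siRNAs against BLM, and in MDA-MB-231 breast cancer cells given a control siRNA or siRNA1. BLM is a RecQ helicase that unwinds recombination intermediates, and the series set out to find the genes it regulates in cancer cells. Each of the 6 groups had 3 libraries, with totals of 30143047 to 40328208 expected counts.

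BLM mRNA fell in every library given a BLM siRNA. In A549 it was 77.9 ± 5.25 CPM in control (SD, n = 3), 1.18 ± 0.0117 with siRNA1, 10.6 ± 0.266 with siRNA2 and 6.47 ± 0.318 with siRNA3, which is 1.51%, 13.6% and 8.30% of control. The control libraries 1 to 3 had 79.2, 82.4 and 72.2 CPM, those with siRNA1 had 1.19, 1.17 and 1.17, those with siRNA2 had 10.3, 10.7 and 10.8, and those with siRNA3 had 6.42, 6.18 and 6.81. In MDA-MB-231, control libraries had 33.5, 35.6 and 35.9 CPM and those with siRNA1 had 5.23, 5.07 and 5.17, a mean of 14.7% of control. The BLM log2 fold changes were -6.04 ± 0.10, -2.88 ± 0.08 and -3.59 ± 0.08 in A549 and -2.76 ± 0.07 in MDA-MB-231 (standard errors, edgeR quasi-likelihood test, largest adjusted p 9.43e-09).

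**Figure D1:**
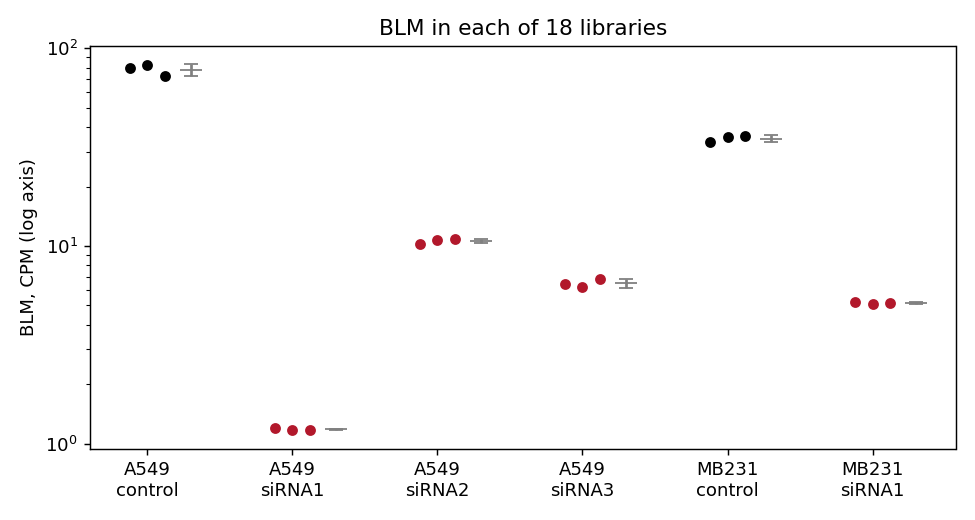
BLM expression in CPM on a log axis for each of 18 libraries (points, black for control siRNA and red for BLM siRNA), with the mean and SD of each group of 3 in grey. A549 libraries with siRNA1 lie at 1.17 to 1.19 CPM, against 72.2 to 82.4 in control.

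In A549 cells given siRNA1, cell division genes fell and p53 target genes rose. All 30 tested G2/M and mitosis genes fell (median log2 fold change -5.39), among them BUB1, a spindle checkpoint kinase (-5.27 ± 0.08), KIF20A, a kinesin of cytokinesis (-5.68 ± 0.09), the spindle gene DLGAP5 (-6.34 ± 0.13) and ANLN, a scaffold of the cleavage furrow (-5.01 ± 0.09). All 36 DNA replication and G1/S genes fell (median -3.25), including the replication initiation factors MCM10 (-5.97 ± 0.10) and CDC6 (-4.98 ± 0.10) and the ribonucleotide reductase subunit RRM2 (-5.62 ± 0.12). Of 29 homologous recombination and Fanconi anaemia genes 28 fell (median -2.14), with FANCD2 at -3.48 ± 0.08 and RAD54L at -4.39 ± 0.15. Of 14 BLM partners and RecQ helicases 13 fell, including BLM itself and the nuclease EXO1 (-5.73 ± 0.13), and 1 rose (without BLM 12 of 13 fell, camera adjusted p 1.16e-10). Of 30 p53 targets 29 rose (median 1.90), with the cell cycle inhibitor CDKN1A at 3.82 ± 0.10, BTG2 at 3.87 ± 0.10, SPATA18 at 5.04 ± 0.12 and TP53I3 at 3.12 ± 0.09. Adjusted over the list alone, these 5 counts were the same, and the 5 calls also held with an estimated correlation (largest adjusted p 0.00164).

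With siRNA1 in A549, 32 of 36 ribosomal protein genes also fell and 1 rose (median -0.71; 33 fell adjusted over the list alone), including RPL3 at -1.77 ± 0.09 and RPL5 at -1.36 ± 0.11, with an adjusted p = 0.57 with an estimated correlation. Of 20 epithelial junction and keratin genes 13 rose, such as the keratin KRT19 (2.61 ± 0.10) and the cadherin CDH1 (1.70 ± 0.10), and 3 fell, such as the tight junction gene CGN (-2.54 ± 0.14), with an adjusted p = 0.11 with an estimated correlation. Of 23 mesenchymal genes 13 rose and 3 fell, the smooth muscle actin gene ACTA2 by 5.64 ± 0.11, TAGLN by 3.16 ± 0.11 and the collagen COL1A1 by 2.57 ± 0.15, with an adjusted p = 0.105 with an estimated correlation. NF-kB and cytokine genes fell in 15 of 23 cases and rose in 3, with NFKB1 at -1.05 ± 0.06 and the chemokine CXCL2 at -2.33 ± 0.20 (adjusted p = 0.324 with an estimated correlation; 16 fell adjusted over the list alone). Stress response genes fell in 11 of 20 cases and rose in 5, led by PHGDH of serine synthesis (-3.57 ± 0.10; adjusted p = 0.357 with an estimated correlation). Cholesterol synthesis genes fell in 12 of 20 cases and rose in 1 (adjusted p = 0.199 with an estimated correlation). Fibroblast markers share COL1A1, COL1A2, COL3A1 and PDGFRB with the mesenchymal list. They rose in 4 of 5 tested cases (adjusted p = 0.199 with an estimated correlation, and camera adjusted p 0.0538 without A549 siRNA3 replicate 3). Luminal breast markers, which share KRT8, KRT18 and KRT19 with the epithelial list, rose in 7 of 10 and fell in 1 (adjusted p = 0.324 with an estimated correlation). Outside the lists, NUF2 of the kinetochore fell by 6.71 ± 0.21 on the log2 scale, and FAM111B fell too (-6.30 ± 0.14). HABP2 went from 3 to 4 counts per control library to 366 to 427, and MUC19, a mucin, from 2 to 6 counts to 417 to 519. In all, 11404 of 15898 tested genes changed, 6196 higher and 5208 lower, and 4786 also moved by at least 1 on the log2 scale. On deposited TPM plus 1 the split was 7689 higher and 3558 lower (68.4% higher against 54.3%), with the median of all genes 0.24 higher.

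siRNA2 in A549 lowered replication and repair genes and raised epithelial genes. Of 36 DNA replication and G1/S genes 35 fell (median -1.10), among them the helicase subunit MCM3 (-2.02 ± 0.07) and MCM10 (-1.88 ± 0.07). Of 29 recombination and Fanconi anaemia genes 25 fell (median -0.66), including FANCC (-1.32 ± 0.08), and of 14 BLM partners 12 fell, including BLM itself and RMI2 (-2.01 ± 0.12; without BLM 11 of 13 fell). Of 30 p53 targets 22 rose and 1 fell (median 0.63; 23 rose adjusted over the list alone), with BTG2 at 2.40 ± 0.10, the sestrin SESN1 at 1.84 ± 0.09 and the death gene BBC3 at 2.08 ± 0.11. Of 20 epithelial genes 14 rose and 2 fell, with EPCAM at 4.53 ± 0.14, KRT19 at 2.37 ± 0.10 and CDH1 at 1.95 ± 0.10. These 5 calls held with an estimated correlation (largest adjusted p 0.0288), as did that of fibroblast markers (adjusted p 0.031). Of these markers 4 of 5 were higher, with COL3A1, also on the mesenchymal list, at 3.28 ± 0.16.

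Of 30 G2/M and mitosis genes 25 fell with siRNA2 (median -0.63), including CDC20 (-1.52 ± 0.11) and the kinase AURKA (-1.31 ± 0.11), with an adjusted p = 0.0646 with an estimated correlation. Interferon-stimulated genes rose in 16 of 29 cases and fell in 3, including IFI44 (3.07 ± 0.20) and the antiviral GTPase MX1 (1.99 ± 0.15; adjusted p = 0.0934 with an estimated correlation; 17 rose adjusted over the list alone). Mesenchymal genes rose in 12 of 23 cases and fell in 4, with ACTA2 at 4.01 ± 0.10 (adjusted p = 0.071 with an estimated correlation). Matrix and integrin genes rose in 17 of 28 cases and fell in 4, led by the matrix protein TNC (5.12 ± 0.21; adjusted p = 0.284 with an estimated correlation; 18 rose adjusted over the list alone). Hypoxia and glycolysis genes fell in 11 of 21 cases and rose in 3, including HK2 (-2.52 ± 0.16) and LDHA (-1.06 ± 0.08; adjusted p = 0.132 with an estimated correlation). Luminal breast markers rose in 7 of 10 cases (adjusted p = 0.0796 with an estimated correlation). CEACAM5, an adhesion molecule, went from 4 to 20 counts per control library to 706 to 920, LGR6 rose by 5.22 ± 0.16, the neuronal pentraxin NPTX1 fell by 5.14 ± 0.12, MARCH4 by 3.08 ± 0.14 and the kinesin KIF5C by 3.33 ± 0.25 on the log2 scale. In all 9680 genes changed, 5172 higher and 4508 lower, and 3037 also moved by at least 1 on the log2 scale. The split was 5510 higher and 3615 lower on TPM plus 1 (60.4% against 53.4%) and 4453 higher and 4602 lower with a filter of 1 CPM, so the majority side changed.

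siRNA3 in A549 lowered cell cycle and repair genes and raised p53 targets and mesenchymal genes. Of 36 DNA replication and G1/S genes 33 fell (median -0.88), such as MCM10 (-1.44 ± 0.07), and of 30 G2/M and mitosis genes 28 fell (median -0.87; 29 adjusted over the list alone), such as the cyclin CCNA2 (-1.42 ± 0.09) and the kinesin KIF11 (-1.30 ± 0.10). Of 29 recombination genes 25 fell (26 adjusted over the list alone), such as RAD54B (-1.25 ± 0.09), and of 14 BLM partners 12 fell, BLM itself included, such as RMI1 (-1.46 ± 0.10; without BLM 11 of 13 fell). Of 30 p53 targets 25 rose (26 adjusted over the list alone), such as SPATA18 (2.65 ± 0.12) and TP53I3 (1.73 ± 0.09). Of 23 mesenchymal genes 15 rose and 1 fell (median 0.89), with ACTA2 at 4.26 ± 0.10, TAGLN at 3.44 ± 0.11 and the protease MMP2 at 3.17 ± 0.12. Of 20 NRF2 targets 15 fell and 1 rose (17 fell adjusted over the list alone), such as GCLC of glutathione synthesis (-2.10 ± 0.09). These 7 calls held with an estimated correlation (largest adjusted p 0.0413).

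Matrix and integrin genes rose in 17 of 28 cases with siRNA3 and fell in 3, including TNC (6.24 ± 0.21) and CYR61 (2.70 ± 0.09; adjusted p = 0.152 with an estimated correlation). Stress response genes fell in 12 of 20 cases and rose in 3 (14 and 4 adjusted over the list alone), including ASNS of asparagine synthesis (-2.51 ± 0.15; adjusted p = 0.282 with an estimated correlation). Cholesterol synthesis genes fell in 13 of 20 cases and rose in 1 (14 and 3 adjusted over the list alone; adjusted p = 0.121 with an estimated correlation). Immediate early genes rose in 9 of 14 cases and fell in 3, with JUN at 2.98 ± 0.08 (adjusted p = 0.396 with an estimated correlation). CDH1 fell by 3.57 ± 0.12 on the log2 scale, CLDN4 of tight junctions rose by 2.29 ± 0.11, and the epithelial list as a whole was not called (5 higher, 5 lower). IL32 rose by 4.10 ± 0.14 and CREB5 by 6.18 ± 0.23, while the receptor ERBB3 fell by 3.95 ± 0.19 and UNC13A by 4.72 ± 0.17 on the log2 scale. In all 9746 genes changed, 4913 higher and 4833 lower, and 3178 also moved by at least 1 on the log2 scale. With DESeq2 size factors 4752 were higher and 5021 lower, so the majority side changed. Replicate 3 of this group stood apart: its deviation from the group mean had an SD of 0.243 over genes, against 0.0617 to 0.161 in the other 17 libraries, and correlated with transcript length across genes (Spearman -0.794). Without it 10307 genes changed, and 12 in place of 11 lists were called.

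Averaged over the 3 siRNAs, all 30 G2/M genes and all 36 replication genes were lower in A549, and 29 of 30 p53 targets were higher. Of 23 mesenchymal genes 17 were higher and 3 lower (adjusted p 0.0153 with an estimated correlation). Of 5 fibroblast markers, some of them on both lists, 4 were higher (adjusted p = 0.174 with an estimated correlation). The genes changed the same way by all 3 siRNAs numbered 4580, 2364 higher and 2216 lower, and another 1132 were called with all 3 siRNAs but not with the same sign. Independent lists of these sizes would share 622.9 higher and 448.9 lower. Unchanged groups simulated against the same controls shared 0, but no effect was simulated, so few or no genes were there to share. That 0 therefore does not measure what the shared controls add to the 4580. Among the shared genes with the largest mean changes, ACTA2 rose by 4.64 ± 0.10, SPOCK3 by 4.66 ± 0.26, TNC by 4.35 ± 0.20 and COL17A1, a hemidesmosome collagen, by 4.18 ± 0.12. TERT, the telomerase catalytic subunit, fell by 3.34 ± 0.14, NPTX1 by 3.26 ± 0.07 and the transcription factor E2F2 by 2.92 ± 0.09 on the log2 scale. MCM10 (-3.10 ± 0.06), PBK (-2.88 ± 0.08), HMMR (-2.83 ± 0.08) and NUF2 also fell, but were not called in a model of 9 siRNA against 3 control libraries. JUN rose by 2.38 ± 0.07, BTG2 by 2.72 ± 0.09 and CDKN1A by 2.15 ± 0.09, and PHGDH fell by 2.19 ± 0.07 on the log2 scale. The mean effect was called for 10719 genes, 5631 higher and 5088 lower, for 3027 with a change of at least 1 on the log2 scale, and for 4957 in the model of 9 against 3. On TPM plus 1 the split was 6580 higher and 3938 lower (62.6% against 52.5%), with the median of all genes 0.10 higher. It was 5333 higher and 5411 lower with DESeq2 size factors and 5393 and 5528 without a filter on low counts, so the majority side changed.

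Fold changes of the siRNA pairs correlated across genes, which are not independent replicates, at Pearson 0.698 (siRNA1 and siRNA2), 0.486 (siRNA1 and siRNA3) and 0.41 (siRNA2 and siRNA3), with Spearman 0.717, 0.516 and 0.456. Unchanged groups against the same controls gave Pearson 0.485, 0.487 and 0.474. The covariances were 0.902, 0.658 and 0.407, against 0.0220, 0.0223 and 0.0218 simulated. The simulated covariance holds the noise that shared controls add under the fitted spread, and the excess over it was 0.880, 0.636 and 0.385. Pearson was no higher than simulated for siRNA1 and siRNA3 and for siRNA2 and siRNA3. The controls have 3 libraries, which may be technical, and were not split. A deviation common to all control libraries is not simulated, so part of the excess may still come from the shared controls.

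Tested directly, siRNA1 and siRNA2 differed most in cell division genes. All 30 G2/M genes were lower with siRNA1 than with siRNA2 (median difference -4.58), including KIF20A (-5.72 ± 0.09), DLGAP5 (-5.79 ± 0.13) and KIF2C (-5.70 ± 0.13), and all 30 were lower than with siRNA3 (median -4.47). SCARA5 was higher with siRNA1 than with siRNA3 (difference 5.86 ± 0.24), and GRIN2C was higher with siRNA1 than with siRNA2 by 5.36 ± 0.24. Between siRNA2 and siRNA3, epithelial genes were higher with siRNA2 in 13 of 20 cases (14 adjusted over the list alone) and lower in 2 (adjusted p = 0.0771 with an estimated correlation), and mesenchymal genes were lower in 15 of 23 and higher in 4 (adjusted p = 0.132 with an estimated correlation). Luminal breast markers were higher with siRNA2 in 7 of 10 cases and lower in 1 (adjusted p = 0.177 with an estimated correlation). NRF2 targets were higher in 12 of 20 and lower in 4 (adjusted p = 0.401 with an estimated correlation) and fibroblast markers higher in 3 of 5 (adjusted p = 0.364 with an estimated correlation). The fibroblast call was lost without A549 siRNA3 replicate 3 (camera adjusted p 0.0816) and with the replicate number as a block (0.0604). HLA-DMB was higher with siRNA2 by 5.90 ± 0.26 and RRAD was lower (-5.24 ± 0.17), and CEACAM5 had 706 to 920 counts with siRNA2 against 0 to 6 with siRNA3. The differing genes numbered 8905 for siRNA1 and siRNA2, 10596 for siRNA1 and siRNA3 and 9383 for siRNA2 and siRNA3.

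**Figure D2:**
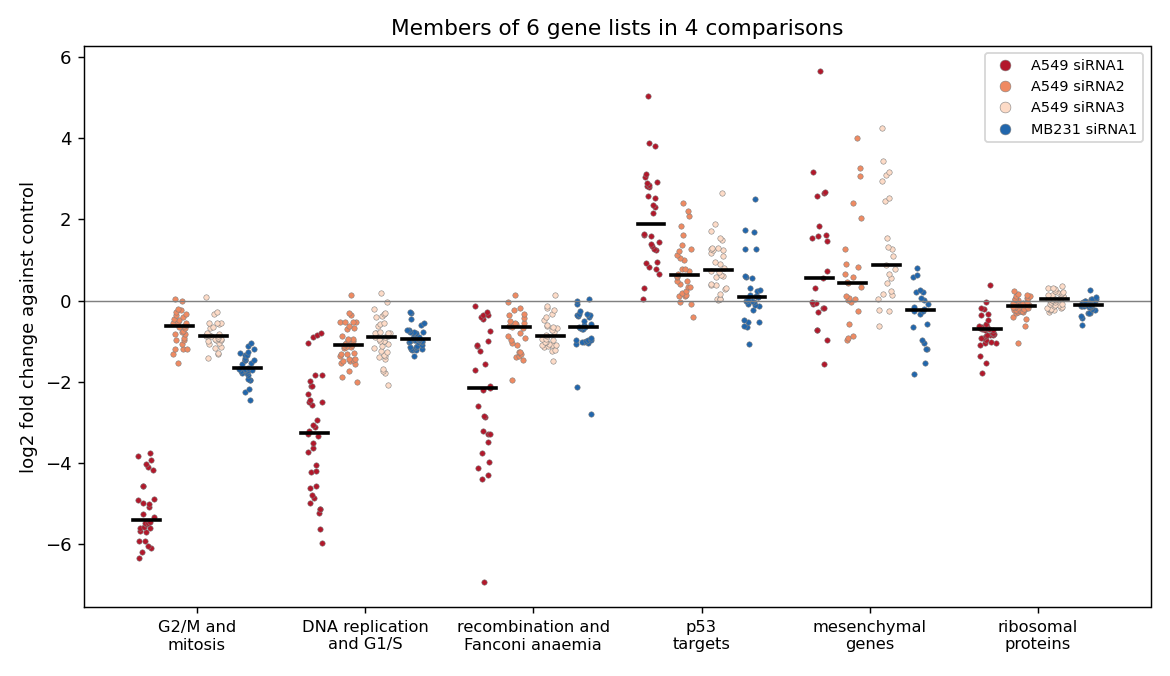
Log2 fold change against control of each tested member (points) of 6 gene lists, with the list median as a black bar, for 3 siRNAs in A549 and siRNA1 in MDA-MB-231 (MB231). The G2/M medians are -5.39 with siRNA1 in A549 and -1.67 in MDA-MB-231.

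In MDA-MB-231 cells, siRNA1 lowered cell division, recombination and matrix genes. All 30 G2/M and mitosis genes fell (median -1.67), including CENPF of the kinetochore (-1.69 ± 0.04), the cyclin CCNB1 (-1.78 ± 0.05) and the spindle protein NUSAP1 (-2.45 ± 0.06). Of 29 recombination and Fanconi anaemia genes 26 fell, including the helicase BRIP1 (-2.13 ± 0.08) and FANCD2 (-1.05 ± 0.05). Of 14 BLM partners 11 fell and 1 rose (12 fell adjusted over the list alone), with EXO1 at -1.10 ± 0.07, BLM itself included. Without BLM 10 of 13 fell, with an adjusted p = 0.0925 with an estimated correlation. Matrix and integrin genes fell in 18 of 28 cases and rose in 4, including CTGF (-1.24 ± 0.05), THBS1 (-1.29 ± 0.06) and TNC (-1.07 ± 0.05). These 4 calls held with an estimated correlation (largest adjusted p 0.0441). All 36 DNA replication and G1/S genes fell (median -0.95), with CDC6 at -1.37 ± 0.05 and RRM2 at -1.22 ± 0.06 (adjusted p = 0.0745 with an estimated correlation).

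Several stress and signalling lists rose in MDA-MB-231, each losing its call with an estimated correlation. Hypoxia and glycolysis genes rose in 17 of 21 cases and fell in 1 (2 adjusted over the list alone), with the growth factor VEGFA at 1.62 ± 0.05, the glucose transporter SLC2A3 at 2.04 ± 0.07 and PGK1 of glycolysis at -1.67 ± 0.05 (adjusted p = 0.146 with an estimated correlation). Integrated stress genes rose in 14 of 20 cases and fell in 5, with CHAC1 at 2.71 ± 0.13, the transcription factors DDIT3 at 1.94 ± 0.09 and ATF3 at 2.19 ± 0.10 (adjusted p = 0.0989 with an estimated correlation). NF-kB and cytokine genes rose in 17 of 24 cases and fell in 5, with IL6 at 1.78 ± 0.06 and CXCL3 at 2.01 ± 0.08, and NRF2 targets rose in 12 of 19 and fell in 1, with HMOX1 of haem breakdown at 2.15 ± 0.11 and TXNRD1 at 0.95 ± 0.04 (both adjusted p = 0.0989 with an estimated correlation). Immediate early genes rose in 12 of 16 cases and fell in 1, with EGR3 at 3.28 ± 0.21 and JUNB at 1.57 ± 0.08 (adjusted p = 0.0745 with an estimated correlation). Interferon-stimulated genes rose in 21 of 34 cases and fell in 4 (22 rose adjusted over the list alone), with IFIT1 at 0.94 ± 0.06 and the RNA sensor IFIH1 at 1.04 ± 0.07 (adjusted p = 0.165 with an estimated correlation). Cholesterol synthesis genes fell in 12 of 20 cases and rose in 2 (adjusted p = 0.105 with an estimated correlation). Luminal breast markers fell in 7 of 12 cases (adjusted p = 0.105 with an estimated correlation) and alveolar type 2 markers in 3 of 4 (adjusted p = 0.165 with an estimated correlation; camera adjusted p 0.0590 with the replicate number as a block and 0.103 without MDA-MB-231 control replicate 3). That library deviated most from its group in this line (SD over genes 0.140, against 0.0826 and 0.0914 in the other controls). Without it 9337 genes changed and 13 in place of 14 lists were called.

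The p53 targets were not called as a list in MDA-MB-231 (11 higher, 6 lower, 12 not past the threshold, camera adjusted p 0.156), with CDKN1A at 1.28 ± 0.08, BBC3 at 1.70 ± 0.12 and the polymerase POLH at -1.07 ± 0.05. Nor were mesenchymal genes (5 higher, 10 lower; 6 and 11 adjusted over the list alone; camera adjusted p 0.366), with VIM at -0.65 ± 0.04 and LOX at -1.20 ± 0.09. The prostaglandin synthase PTGS2 rose from 138 ± 49.1 to 1943 ± 132 CPM (SD, n = 3), a log2 fold change of 3.81 ± 0.21, the receptor ACKR3 by 3.15 ± 0.28 and the heat shock gene HSPA6 by 3.03 ± 0.18. CAVIN2 fell by 2.97 ± 0.06, KISS1 by 2.85 ± 0.21, the vitamin D hydroxylase CYP24A1 by 2.81 ± 0.10 and the fatty acid desaturase FADS2 by 2.78 ± 0.12 on the log2 scale. In all 8457 of 15280 genes changed, 4208 higher and 4249 lower, and 1237 also moved by at least 1 on the log2 scale. On TPM plus 1 the split was 4971 higher and 3317 lower (60.0% against 49.8%). With limma-voom it was 4256 and 4232, so the majority side changed.

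With siRNA1 in both lines, RPS9, a protein of the small ribosomal subunit, fell from 446 ± 46.2 to 18.95 ± 2.26 CPM in A549 (log2 fold change -4.56 ± 0.13) and by 3.03 ± 0.09 on the log2 scale in MDA-MB-231. With siRNA2 and siRNA3 in A549, RPS9 had log2 fold changes of 0.14 ± 0.11 and -0.01 ± 0.11, neither past the threshold, and siRNA1 differed from each (-4.70 ± 0.13 and -4.54 ± 0.13, larger adjusted p 7.89e-12). HADHA of fatty acid oxidation fell with siRNA1 by 3.25 ± 0.09 and 2.38 ± 0.06, the dynein light chain DYNLT1 by 3.71 ± 0.16 and 2.77 ± 0.09, the transporter ABCG2 by 2.99 ± 0.07 and 2.43 ± 0.09, and HAUS1 of the spindle by 3.63 ± 0.15 and 2.85 ± 0.09 on the log2 scale, in A549 and MDA-MB-231. NUSAP1 fell by 5.92 ± 0.11 in A549. The metallothionein MT1F rose by 3.33 ± 0.18 and 3.51 ± 0.21, SESN2 by 2.84 ± 0.12 and 2.51 ± 0.10, the dynein heavy chain DNAH7 by 2.48 ± 0.15 and 2.70 ± 0.16, GDF15 by 2.51 ± 0.12 and 1.71 ± 0.09 and BBC3 by 3.04 ± 0.11 and 1.70 ± 0.12. Of 14300 genes tested in both lines, 2158 were higher in both (1506 for independent lists, odds ratio 2.57, 95% interval 2.38 to 2.77, Fisher's exact test) and 2296 were lower in both (1381, odds ratio 3.91, interval 3.62 to 4.23), 4454 in all, while 933 and 714 changed in opposite directions. These intervals count genes as independent, which they are not, and do not measure the spread between libraries. With a change of at least 1 on the log2 scale in both, 543 moved the same way. The fold changes of the lines correlated at Pearson 0.376 and Spearman 0.356 across genes, and those of MDA-MB-231 correlated at 0.124 and 0.0655 with siRNA2 and siRNA3 in A549.

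**Figure D3:**
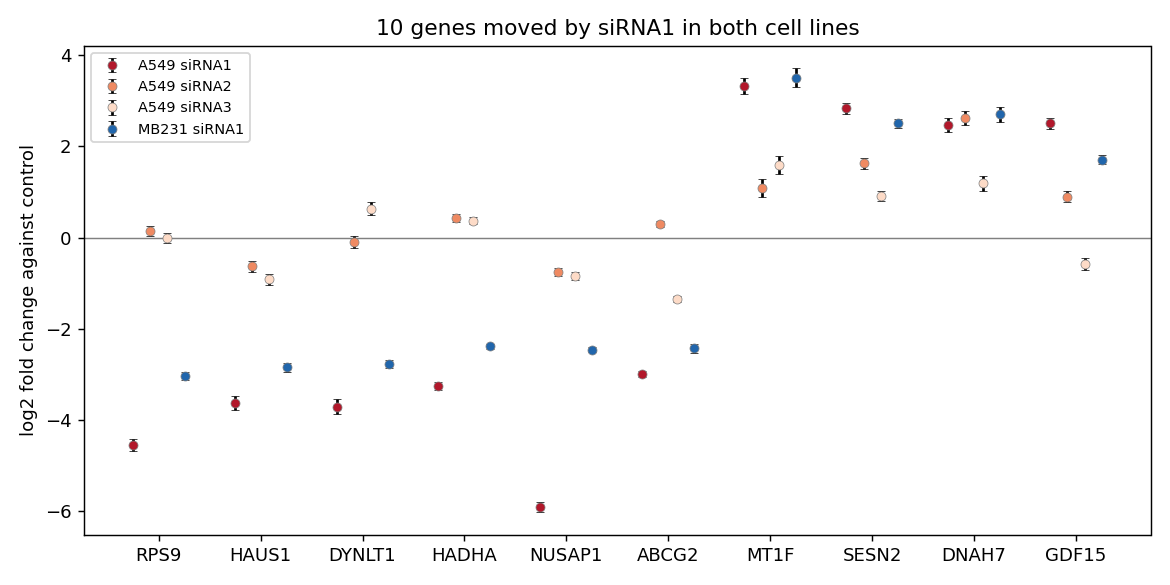
Log2 fold change against control with its standard error for 10 genes moved by siRNA1 in both lines, in 3 siRNA comparisons in A549 and in MDA-MB-231 (MB231). RPS9 lies at -4.56 and -3.03 with siRNA1 and at 0.14 and -0.01 with siRNA2 and siRNA3.

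The effect of siRNA1 differed between the lines most in cell division and DNA replication genes, followed by p53 targets. The labels do not say whether both lines were grown in the same type of culture. A difference between lines therefore cannot be separated from one between culture types. All 30 G2/M genes fell further in A549 (median difference -3.49), including UBE2C of the mitotic ubiquitin pathway (-4.58 ± 0.11) and BUB1 (-3.65 ± 0.09), and 33 of 36 replication genes did, with 1 the other way (median -2.27), including MCM10 (-4.91 ± 0.10). BLM itself fell further in A549 by a difference of -3.23 on the log2 scale. Of 30 p53 targets 28 had differences above 0 and 1 below (median 1.84), including TP53I3 (2.60 ± 0.09), CYFIP2 (3.35 ± 0.12) and MDM2, the ubiquitin ligase of p53 (3.36 ± 0.14). Mesenchymal genes had differences above 0 in 15 of 24 cases and below in 3, including ACTA2 (5.94 ± 0.15), and epithelial genes above 0 in 13 of 21 and below in 2, including KRT19 (2.78 ± 0.11). Stress response genes had differences below 0 in 17 of 20 cases, including ASNS (-3.16 ± 0.12). These calls held with an estimated correlation (largest adjusted p 0.0181). Luminal breast markers, which share keratins with the epithelial list, also had a median difference above 0 (1.16, adjusted p 0.027 with an estimated correlation). So did alveolar type 2 markers (1.74, adjusted p 0.0659 with an estimated correlation). NF-kB and cytokine genes had differences below 0 in 17 of 24 cases and above in 3 (18 and 4 adjusted over the list alone), including CXCL3 (-3.23 ± 0.14), and matrix genes above 0 in 19 of 28 and below in 7, including THBS1 (2.95 ± 0.11), both with an adjusted p = 0.0659 with an estimated correlation. NRF2 targets had differences below 0 in 11 of 20 cases and above in 3, including HMOX1 (-2.77 ± 0.14; adjusted p = 0.11 with an estimated correlation). In all 9673 of 16736 genes differed, 5158 above 0 and 4515 below, and 4040 by at least 1 on the log2 scale. On TPM plus 0.1 the split was 6475 and 3680 (63.8% above 0 against 53.3%), and with a filter of 1 CPM it was 4370 and 5080 (46.2%), so the majority side changed. With all 18 libraries it was 4252 and 4938 (46.3%).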

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

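No test in this part was chosen after its result was seen. The results listed here differed between the cell lines by the interaction test of edgeR, A549 minus MDA-MB-231, for siRNA1. The number of genes that differed was 9673. Among the lists called by camera the median differences were -1.45 for BLM partners, -1.18 for recombination and Fanconi anaemia genes, 1.84 for p53 targets, -2.27 for DNA replication and G1/S, -3.49 for G2/M and mitosis, -0.88 for NF-kB and cytokines, -0.71 for the stress responses, -0.54 for hypoxia and glycolysis, -0.35 for NRF2 targets, 1.27 for epithelial genes, 1.40 for mesenchymal genes, 0.67 for matrix and integrins, -0.60 for ribosomal proteins, 1.74 for alveolar type 2 markers and 1.16 for luminal breast markers. With an estimated correlation 9 of these 15 calls held, and those for hypoxia (adjusted p = 0.193), NRF2 targets (adjusted p = 0.11), ribosomal proteins (adjusted p = 0.249) and NF-kB, matrix and alveolar type 2 genes (each adjusted p = 0.0659) did not.

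BLM differed by -3.23, ACTA2 by 5.94, KRT19 by 2.78, THBS1 by 2.95, MDM2 by 3.36, CYFIP2 by 3.35, TP53I3 by 2.60, MCM10 by -4.91, UBE2C by -4.58, BUB1 by -3.65, CXCL3 by -3.23, ASNS by -3.16 and HMOX1 by -2.77 on the log2 scale. The genes with the largest fitted differences had few or no counts in at least 1 group, so that their values depend on the prior count and are no bounds. HABP2 (8.90, 0 to 1 counts in MDA-MB-231 libraries), MUC19 (7.13, 0 to 3 counts), NPTX1 (-6.83, 0 to 4), MMP17 (-6.20, 0 to 4) and TRPA1 (-5.96, 0 to 11) were near 0 in MDA-MB-231, and PGM5 (8.15) had 0 to 2 counts in A549 control libraries. The difference of HABP2 was no longer called without MDA-MB-231 control replicate 3 (6.89, adjusted p 1.00, against adjusted p of 2.72e-11 to 0.00745 under its other alternatives). LOC102723360 (-12.86), GSTT2 (-7.23) and the pair LOC100132062 and LOC100132287 (8.37 each, with the same counts) are uncertain. They may share reads with near copies, which was not tested.

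Other splits of the same libraries were counted for each number of called genes. Comparisons of 3 against 3 libraries have 10 splits, which cannot give a share under 0.05. In fits of the compared groups alone, the real values were 11748 for siRNA1, 10643 for siRNA2 and 8919 for siRNA3 in A549, 9529, 9482 and 8348 for siRNA1 against siRNA2, siRNA1 against siRNA3 and siRNA2 against siRNA3, and 8457 in MDA-MB-231, and the highest other split gave 0 in each. For the genes changed the same way by all 3 siRNAs, 1 of 100 splits, the real one, was as large (4580, highest other 2017). The same held for the interaction (9673, 1 of 100, highest other 8261). For the mean effect in the model of 9 against 3 it was also 1 of 100, but the highest other split was nearly as large (4957, highest other 4853). The other splits regroup libraries of groups that differ, and libraries of a group may be technical, so these shares cannot exclude chance. For the genes changed the same way in both lines (4499 in fits of the compared groups, highest other 0 of 100 splits) such a count decides nothing, since the other splits of each line called 0 genes and left none to share.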

How the results depend on the processing

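The runs of gene lists without A549 siRNA3 replicate 3, without MDA-MB-231 control replicate 3 and without BLM were added after the data had been seen, and the other alternatives were fixed earlier. Of 1694 recomputed values of 174 named gene results, 1690 kept their direction and their side of the threshold, 0 reversed, and 4 lost the call, all in the A549 mean under the model of 9 against 3 libraries: MCM10 (-2.20, adjusted p 0.0566), NUF2 (-1.71, 0.196), PBK (-1.82, 0.137) and HMMR (-1.72, 0.165), against adjusted p of at most 3.80e-08 under the other alternatives of the 4. This model puts the differences between the siRNAs into the spread, and under it the count was 4957. Of 1248 values with 1 library left out, 1247 kept the call, and HABP2 in the interaction did not (6.89 without MDA-MB-231 control replicate 3). A minimum absolute log2 fold change of 1, which removes smaller changes, left 4786, 3037 and 3178 genes for siRNA1, siRNA2 and siRNA3 in A549, 3027 for their mean, 911 for all 3 alike, 1237 in MDA-MB-231, 543 in both lines and 4040 in the interaction. Of 157 recomputed counts, 133 stayed within 1.5 times. With an estimated correlation, the lists called were 5 in place of 13 (siRNA1), 6 of 12 (siRNA2), 7 of 11 (siRNA3), 6 of 15 (mean), 5 of 8 (siRNA1 minus siRNA2), 5 of 11 (siRNA1 minus siRNA3), 0 of 5 (siRNA2 minus siRNA3), 4 of 14 (MDA-MB-231) and 9 of 15 (interaction). With fry, which does not compare a list with other genes, they were 20, 20 and 19 for the 3 siRNAs, and 20, 18 and 19 between them.

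With 1 library left out, counts ran from 10666 to 11260 (siRNA1), 8747 to 9232 (siRNA2), 8864 to 10307 (siRNA3), 9552 to 11549 (mean), 3876 to 5111 (all 3 alike), 7875 to 8775, 9823 to 10910 and 8487 to 9784 (siRNA1 against siRNA2, siRNA1 against siRNA3, siRNA2 against siRNA3), 7194 to 9337 (MDA-MB-231), 9157 to 10083 (interaction) and 3902 to 4671 (both lines), and BLM from -6.10 to -6.00, -2.93 to -2.84, -3.65 to -3.55 and, in MDA-MB-231, -2.80 to -2.75. Without A549 siRNA3 replicate 3, 12 lists were called for siRNA3, 15 for the mean, 12 for siRNA1 minus siRNA3 and 5 for siRNA2 minus siRNA3. This ended the calls of fibroblast markers for siRNA1 (adjusted p 0.0538) and siRNA2 minus siRNA3 (0.0816), and added alveolar type 2 markers for siRNA3 (0.0431), matrix genes for siRNA1 minus siRNA2 (0.0267), mesenchymal genes for siRNA1 minus siRNA3 (0.0129) and stress response genes for siRNA2 minus siRNA3 (0.0297). Without MDA-MB-231 control replicate 3, 13 lists were called in MDA-MB-231, where alveolar type 2 markers lost the call (adjusted p 0.103), and 15 in the interaction. With BLM left out of its own list, the list kept its camera call in 8 comparisons where it had one, and with an estimated correlation lost it in MDA-MB-231 (adjusted p 0.0925). As a replicate block, the numbers gave 11064, 9294 and 9321 genes for the 3 siRNAs, 8376 in MDA-MB-231 and 9381 in the interaction. The numbers did not pair the libraries: of 21 same-numbered pairs, 7 had deviations correlated over 0.1 (-0.76 to 0.553), and 5 correlated best with their own number. The block ended 2 of 104 list calls, fibroblast markers in siRNA2 minus siRNA3 (adjusted p 0.0604) and alveolar type 2 markers in MDA-MB-231 (0.059), and turned 0. It added the call of mesenchymal genes in siRNA1 minus siRNA3 (camera adjusted p 0.0445, against 0.0519 without the block). No called list median changed sign under the other scalings, filters, tests, designs and TPM runs in the 3 siRNA comparisons against control in A549, their mean, MDA-MB-231 and the interaction (0 cases; not examined between siRNAs), and of 16 list results whose median, mean and test differed in sign 0 were called. Over 156 of 198 list and comparison pairs, counts adjusted over the list alone were the same. The median of all genes moved by 0.24 to 0.25 on TPM for siRNA1, 0.10 to 0.11 for the mean and 0.12 to 0.13 for the interaction, and by -0.11 for the interaction with all 18 libraries. The cause was not tested. Depth limits genes with few counts in a group, such as HABP2 in MDA-MB-231.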

Other observations

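The rank test of the 7-base word, the pairing test of 38 members, the order of BLM levels and the length test of A549 siRNA3 replicate 3 were chosen after their results were seen, as were the named members outside the rule, RPL23A, SAMM50, NEK1 and MMP1. Among the lists not yet described, the RNA interference machinery was not called with any siRNA in A549 or with siRNA1 in MDA-MB-231 (camera adjusted p 0.761, 0.164, 0.983 and 0.798). Replication-dependent histones, of which 5 could be tested, fell in 5 cases with siRNA1 in A549 and in 4 of 4 in MDA-MB-231 (medians -1.88 and -2.06, camera adjusted p 0.304 and 0.055). Leukocyte markers had 4 tested members and were not called in either line with siRNA1 (camera adjusted p 0.784 and 0.967).

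On the assumption that siRNA1 is the same siRNA in both lines, as its shared name gives it, a set was formed. Its 62 genes fell by at least 1 on the log2 scale with siRNA1 in both lines and by no more than 0.5 with siRNA2 and siRNA3 in A549. A candidate explanation is seed-type off-target repression by siRNA1, whose sequence is not given in the sources used here. The 3' UTR word AATTACA, present once in BLM outside its 3' UTR, ranked first of 15955 words for lower expression with siRNA1 in A549 (z -6.60). It also had rank 1 for lower expression with siRNA1 in MDA-MB-231 (z -8.78), against ranks 3606 and 2952 with siRNA2 and siRNA3 in A549. Other words ranked first with siRNA2 (GGCTCAT, z -8.77) and siRNA3 (ATACCCA, z -7.84), each also present once in BLM outside its 3' UTR. In A549, GGCTCAT had ranks 2033 and 9249 with siRNA1 and siRNA3, and ATACCCA ranks 6778 and 9276 with siRNA1 and siRNA2. Each of the 3 siRNAs thus had a first word of its own. Seed-type off-target repression is therefore a candidate for siRNA2 and siRNA3 too, and was not tested further for them. Presence in BLM alone says little. The word GGGATTA, rank 5 with each of the 3 siRNAs in A549, is also there once outside the 3' UTR. Behind AATTACA with siRNA1 in A549 came GCGCCTG (z -5.62), which also had rank 4 with siRNA2. AATTACA was in 17 of 59 members with a 3' UTR (28.8%, against 15.6% in genes matched on length, permutation p 0.0039), although the word was found on fold changes that include these members. The 42 members without it in the 3' UTR matched 19 bases of BLM around the word better than genes of like length (mean percentile 63.1, permutation p 0.001), with 16 bases in RPS9, RPL23A and FADS2, 15 in HADHA, SAMM50 and NEK1 and 14 in DYNLT1. These 7 have the highest percentiles (98.75 or more), 14 of the 42 lie below 50, and without the 7 the mean is 55.8, so that few members carry much of the excess. Of the 42, 4 have the word elsewhere in the transcript, NEK1 among them, and without them the mean percentile of the other 38 was 61.3 (permutation p 0.0043).

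The G2/M genes fell further with siRNA1 than with siRNA2 or siRNA3 in A549. As the cause of the whole fall, direct seed-type repression through the exact word AATTACA is argued against. The 18 of 30 members without it in the searched transcript had a median of -5.39, against -5.23 in the 12 with it. Other forms of direct repression of these 18 members stay open, since RPS9 and HADHA also fell with siRNA1 without the word. The shifted word ATTACAA, rank 17 with siRNA1 in A549 and rank 2 in MDA-MB-231, was not searched for in the 18 members. Partial pairing of these 18 members with the BLM site was not tested as a set. A trend with GC content and length is argued against too, since its removal left the median difference between siRNA1 and siRNA2 at -4.40 (before -4.58, SD over members 0.902). Lower remaining BLM with siRNA1 stays open: 3 of 3 pairs of siRNAs were ordered alike by the BLM left and by the list median, but the G2/M list was not called between siRNA2 and siRNA3 (camera adjusted p 0.384), and each siRNA has 1 BLM level, so that the level and the siRNA cannot be told apart. In MDA-MB-231 siRNA1 left 14.7% of that line's control BLM, a larger share than any siRNA left in A549. In CPM it left 5.155, less than siRNA2 (10.6) and siRNA3 (6.47) and more than siRNA1 (1.18) in A549. The list median of -1.67 in MDA-MB-231 was below those with siRNA2 (-0.63) and siRNA3 (-0.87) in A549. Whether MDA-MB-231 follows the order thus depends on the measure, and this comparison across lines was not tested. An indirect effect of other genes lowered by siRNA1 was not tested.

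A549 siRNA3 replicate 3 stood apart from replicates 1 and 2. RNA of MDA-MB-231 mixed in is argued against, since 15 genes abundant there and near 0 in replicates 1 and 2 stood at 0.00998% of their MDA-MB-231 level (0.00804% in replicates 1 and 2), with MMP1 at 0.0971 CPM against 3232. Loss of RNA depending on transcript length may explain it, since its deviations correlated with length at -0.794, further from 0 than in the other 17 libraries (-0.577 to 0.694), where centring on a group of 3 gives replicates 1 and 2 the opposite sign. No biological explanation was tested.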
